A study of Homo sapiens with 8 samples.

How the data were processed

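RNA was extracted from Kasumi-1 cells with a Qiagen RNeasy micro kit and libraries were made with the Illumina TruSeq RNA kit, per the labels' protocols, which also state that transduced cells were selected with puromycin. The authors deposited a single table of FPKM values (fragments scaled by transcript length and by mapped fragments) with 23284 gene symbols and 8 libraries. The submitters' processing notes name TopHat, Cufflinks, Cuffdiff and the hg19 genome build, without versions. The annotation and any scaling between libraries are not given in the sources used here. FPKM divides by gene length and library size, so very short genes can reach high values from few fragments. The microRNA gene MIR4461 alone held 9.98% to 13.5% of the summed FPKM of a library. It was high in all 8 libraries, so it is not taken as an example of few fragments. Summed FPKM ran from 733146 to 845178. Genes were taken by the symbols in the table, and no coordinates are given, because the table has none and the reference annotation at hand is of another build than hg19. The kit named does not state strand, and how reads shared between near-identical genes such as HBG1 and HBG2 or HBA1 and HBA2 were divided is not given, so single values of such pairs are uncertain.

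Groups and replicate numbers came from the sample titles. The 28 pairs of libraries shared at most 1 identical nonzero value, so each library was counted as a separate sample. FPKM values are not counts. Their steps were examined in genes below 0.5 FPKM in every library: 73.4% to 76% of the ratios between a library and PLKO replicate 2, after scaling by the most frequent ratio, lay within 0.5% of a ratio of whole numbers up to 6. The value of 1 fragment was 1.0 to 2.57 times that in PLKO replicate 2, which gives the relative depth. Steps depend on each gene's length and isoforms, so reads were not recovered. Fewer fragments make low genes less precise in SCR replicate 1 (38.9% of the depth of PLKO replicate 2), untreated replicate 1 (48.5%) and PLKO replicate 1 (55.5%) than in MEIS2_KD replicate 1 (83.9%) or untreated replicate 2 (78.5%), with SCR replicate 2 at 69.5% and MEIS2_KD replicate 2 at 58.6%.

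Values were transformed to log2(FPKM + 1), and fold changes are on that scale, which understates the change of low genes. Genes with a mean of at least 1 FPKM over the 8 libraries were kept (11646). A limma (version 3.58.1, R 4.3.3) linear model with 4 groups and 4 residual degrees of freedom, with eBayes trend and robust options, gave 6 contrasts. Benjamini-Hochberg adjusted p below 0.05 was the threshold, and the adjusted p and SE of a gene come from this model unless another fit is named. A 0 in the table can be a failed estimate, so genes listed at 0 are given per library and without a fold against a group at 0. For 22 gene lists (601 symbols, all found), written from general knowledge before the data were examined, limma camera with a preset correlation of 0.01 was used, adjusted over the lists, with camera with an estimated correlation and fry as alternatives. With an estimated correlation camera uses the residual degrees of freedom (4 in the main fit), with the preset the number of genes. A call lost with an estimated correlation therefore need not mean a larger correlation. The estimate was below the preset for the p53 (-0.021), cholesterol (-0.037) and erythroid (-0.048) lists, and above it for others such as G2/M (0.147). Members called were counted over all genes and adjusted over the list alone. Some lists share members, such as GATA1, LDHA and BBC3.

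The genes named followed a rule fixed before the data were examined: MEIS2, RUNX1, RUNX1T1 and YES1; for MEIS2_KD against SCR the 12 largest rises and 12 largest falls among called genes with both libraries outside all 6 controls; up to 4 members of each list by smallest p, of which mostly the first 2 are given; and up to 5 rises and 5 falls in each other comparison, symbols of small RNAs and unnamed loci being passed over. Other genes are named after their values were seen. Small RNA genes were recognised by symbol (microRNA, snoRNA and similar) and remained in the tests.

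The model was tested on simulated data with the means and spreads of the 11646 genes. For MEIS2_KD against SCR, with 200 changed genes in each of 3 runs, 88.3% of genes changed by log2 1 and 98% of those changed by log2 2 were recovered, and 4.3% of calls were false. Overlaps between comparisons that share libraries were simulated with unchanged groups in 50 sets. All simulated genes were drawn independently, without shared library effects or differences in depth. Numbers from unchanged groups may therefore be too low for real libraries. They also do not cover data in which SCR alone differs. Alternatives were pseudocounts of 0.1 and 0.5, no filter or a mean of at least 5 FPKM, eBayes without trend or robust, quantile and upper quartile scaling, the replicate number as a block, each library left out, only the compared groups, at least 1.5-fold, and the mean of the 3 control groups. Leaving out the SCR libraries or small RNA genes was added after the data were seen. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.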

Results

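Gene expression was measured by RNA sequencing in Kasumi-1, an established acute myeloid leukaemia cell line carrying the t(8;21) translocation, which fuses RUNX1 (AML1) to RUNX1T1 (ETO). The 8 libraries formed 4 groups of 2: untreated cells, cells carrying the PLKO lentiviral backbone, cells carrying a scrambled shRNA (SCR), and cells labelled as carrying an shRNA against MEIS2, a homeobox transcription factor (MEIS2_KD). Each library listed an FPKM value for 23284 gene symbols, of which 14571 to 15678 were above 0 and 11161 to 11704 reached 1 FPKM. Read totals are unknown, but the smallest steps of the FPKM values put the relative depth of the libraries between 38.9% (SCR replicate 1) and 100% (PLKO replicate 2, the deepest). The labels do not say whether replicates came from separate cultures, so p-values of genes measure only the spread between these libraries. Camera p-values with the preset correlation compare a list's genes with the other genes. Very small ones therefore reflect numbers of genes rather than replication. The question put by the design was which transcripts change when MEIS2 is knocked down.

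The targeted gene was examined first. MEIS2 stood at 5.52 and 4.91 FPKM in the untreated libraries, 5.23 and 4.84 with the backbone, 5.84 and 6.96 with the scrambled shRNA, and 3.72 and 5.48 in the libraries labelled MEIS2_KD. Replicate 1 of that group therefore lay below all 6 control libraries, whereas replicate 2 lay above 3 untreated and backbone libraries. The log2 change of MEIS2 was -0.42 ± 0.173 (SE) against SCR, with an adjusted p of 0.22 by limma, -0.13 against PLKO (adjusted p = 0.937) and -0.17 against untreated (adjusted p = 0.801). A lower MEIS2 transcript was therefore not established in this group, and the name MEIS2_KD below is the label of the libraries, not a measured state. YES1, which encodes a Src family kinase, stood at 4.89 and 4.94 FPKM in untreated cells, 7.91 and 5.31 with PLKO, 9.13 and 9.66 with SCR, and 4.59 and 7.41 in the libraries labelled MEIS2_KD. Its difference from SCR, -0.60 on the log2 scale, did not pass (adjusted p = 0.174). RUNX1 averaged 43.6 ± 3.56 FPKM in untreated cells, 35.3 ± 0.422 with SCR and 43.5 ± 11.2 in MEIS2_KD (SD, n = 2). RUNX1T1 averaged 26.6 ± 0.956, 20.0 ± 0.632 and 24.8 ± 2.97 FPKM in the same groups (SD, n = 2). Neither differed from SCR by limma, with an adjusted p of 0.409 for RUNX1 and 0.201 for RUNX1T1.

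**Figure D1:**
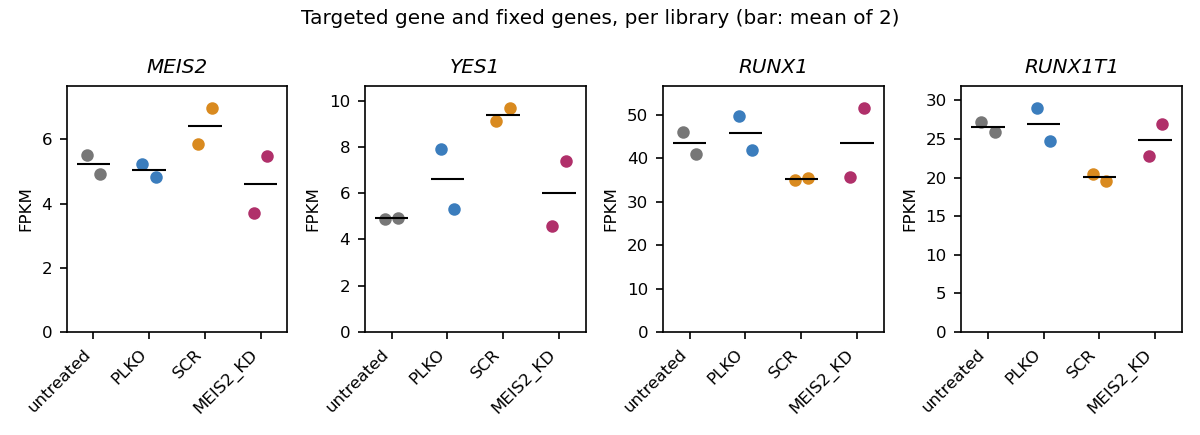
FPKM of MEIS2, YES1, RUNX1 and RUNX1T1 in each of the 8 libraries (points) by group, with the mean of the 2 libraries as a bar. The MEIS2_KD libraries differ from each other in MEIS2 (3.72 and 5.48 FPKM), and the higher value lies within the range of the untreated libraries.

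The planned main comparison set MEIS2_KD against the scrambled shRNA. Genes of red cells and keratins were far lower in the libraries labelled MEIS2_KD than in SCR, whereas 4 of 15 primary granule genes and 3 of 15 mature granulocyte and monocyte genes were called higher, neither list being called with an estimated correlation. Of 11646 genes tested by limma, 779 were called at an adjusted p below 0.05, 165 higher and 614 lower. The embryonic and fetal globin transcripts led the lower genes: HBE1 was listed at 522 and 469 FPKM in the SCR libraries and at 0 in both MEIS2_KD libraries, and HBG2 at 470 and 456 against 0 and 0. These globins were also at 0 in both untreated libraries, and in the backbone libraries HBE1 stood at 25.5 and 23.5 FPKM and HBG2 at 26.5 and 29.4. MS4A3, a marker of granulocyte-monocyte progenitors, was at 8.99 ± 1.11 FPKM in MEIS2_KD against 1.45 ± 0.595 in SCR and 4.07 ± 0.36 in untreated cells (SD, n = 2).

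The erythroid list held 20 tested genes, of which 17 fell and 1 rose in MEIS2_KD against SCR. Adjusted over the list alone, 18 fell and 1 rose. The limma camera test gave an adjusted p of 2.27e-28 for the list, and 0.00538 with an estimated correlation. HBZ, a zeta globin, was at 334 and 314 FPKM in SCR and at 0 in both MEIS2_KD libraries, and RHAG, a red cell membrane protein, at 104 and 110 against 0 and 0. Against untreated cells the list gave 0 calls (1 lower at an unadjusted p below 0.05) and a median log2 difference of 0.00, whereas 17 of the 20 genes were called higher in SCR than in untreated cells. GATA1 and GFI1B, transcription factors of the red cell and platelet lineages, were also lower than in SCR, GATA1 by a log2 change of -4.23 and GFI1B with 5.93 and 6.16 FPKM in SCR and 0 in both MEIS2_KD libraries. GATA1 was listed at 0 and 0.114 FPKM in untreated cells, 0.968 and 0.269 with PLKO, 19.6 and 17.9 with SCR, and 0.107 and 0 in MEIS2_KD.

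The keratin genes KRT8, KRT18 and KRT19 and the homeobox genes HOXB2, HOXB4 and HOXB9 were also lower in MEIS2_KD than in SCR. Among the 6 tested fibroblast and epithelial genes KRT8, KRT18 and KRT19 fell, 3 also when adjusted over the list alone (camera adjusted p = 0.000536; adjusted p = 0.124 with an estimated correlation). KRT8 averaged 72.4 ± 0.221 FPKM in SCR, 1.54 ± 0.245 in MEIS2_KD and 1.84 ± 0.505 in untreated cells (SD, n = 2). KRT19 was listed at 22.0 and 22.6 FPKM in SCR, 0.162 and 0.361 in PLKO, and 0 in the 4 untreated and MEIS2_KD libraries. The TALE and HOX list had 14 tested genes with 3 lower and 0 higher, the same counts when adjusted over the list alone, and a camera adjusted p of 0.829. HOXB9 (17.6 and 14.7 FPKM) and HOXB2 (6.51 and 6.12 FPKM) were seen in SCR and listed at 0 in untreated and MEIS2_KD libraries. The list of megakaryocyte, mast cell and basophil genes had 5 tested members, of which GP1BB and GATA1 fell, 2 also when adjusted over the list alone (camera adjusted p = 0.0108; adjusted p = 0.227 with an estimated correlation). GP1BB, a platelet glycoprotein, was at 8.14 and 7.01 FPKM in SCR, 0 in both MEIS2_KD and PLKO libraries, and 0 and 1.25 in untreated cells.

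Granule and mature myeloid lists were called higher in MEIS2_KD than in SCR by camera with the preset correlation. Of 15 primary granule genes 4 rose and 0 fell, 8 rose when adjusted over the list alone, and the camera adjusted p was 7.73e-07 (adjusted p = 0.0689 with an estimated correlation). LYZ, lysozyme, averaged 36.0 ± 1.14 FPKM in MEIS2_KD, 14.4 ± 1.20 in SCR and 21.6 ± 0.628 in untreated cells (SD, n = 2). Of 15 tested mature granulocyte and monocyte genes, S100A8, S100A9 and MNDA rose and the Fc receptor gene FCGR2A fell. Adjusted over the list alone 5 rose and 1 fell, with a camera adjusted p of 0.00557 (adjusted p = 0.111 with an estimated correlation). S100A9, a calcium-binding protein of neutrophils and monocytes, averaged 14.2 ± 3.98 FPKM in MEIS2_KD, 4.15 ± 0.33 in SCR and 3.87 ± 1.63 in untreated cells (SD, n = 2), a log2 change of 1.54 ± 0.253 (SE) against SCR. S100A8 was at 2.54 and 3.04 FPKM in MEIS2_KD, 0.915 and 0 in SCR, and 0 and 0.453 in untreated cells. MNDA, a myeloid nuclear antigen, averaged 36.1 ± 0.236 FPKM against 13.6 ± 1.91 in SCR (SD, n = 2), and FCGR2A 4.96 ± 0.178 against 12.3 ± 0.633 (SD, n = 2). In SCR the primary granule genes themselves lay at a median of 61.8% of their untreated level, 14 of the 15 below it. By camera the primary granule list was not called against PLKO (adjusted p = 0.853) or untreated (adjusted p = 0.273), and neither was the mature list (adjusted p = 0.139 and 0.489).

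Among called genes with both MEIS2_KD libraries above all 6 controls, small RNA genes and unnamed loci passed over, the 12 largest rises were those of MS4A3, S100A9, S100A8, BPI, MNDA, IGLL1, LYZ, SERPINA1, CLEC12A, CSTA, GFRA3 and SERPINB8. BPI, a bactericidal protein of neutrophil granules, changed by 1.38 ± 0.173 on the log2 scale, SERPINA1 (alpha-1 antitrypsin) by 1.19 ± 0.126, the myeloid lectin CLEC12A by 1.17 ± 0.166, the cystatin CSTA by 1.07 ± 0.127, GFRA3 by 1.07 ± 0.149 and SERPINB8 by 1.04 ± 0.246 (SE). The 12 largest falls among genes below all 6 controls were those of HIST1H2BK, NFE2, BST2, EGR1, CTSL1, GMPR, LEPR, PLCD1, UCA1, FLNC, SLC6A8 and HIST2H2BE. HIST1H2BK, a histone, averaged 290 ± 2.63 FPKM in SCR, 6.17 ± 0.0535 in MEIS2_KD, 21.4 ± 2.78 in PLKO and 8.53 ± 0.548 in untreated cells (SD, n = 2). NFE2, a transcription factor of red cells and platelets, averaged 37.5 ± 3.60 FPKM in SCR against 0.547 ± 0.373 in MEIS2_KD and 0.912 ± 0.136 in untreated cells (SD, n = 2). CTSL1 (log2 -3.28 ± 0.178), GMPR (-3.26 ± 0.219), LEPR (-3.26 ± 0.165), PLCD1 (-3.15 ± 0.164), UCA1 (-3.15 ± 0.169), SLC6A8 (-2.77 ± 0.151) and HIST2H2BE (-2.62 ± 0.181, SE) were likewise high in SCR. FLNC, a filamin, was listed at 0 in both MEIS2_KD libraries and at 6.36 and 5.95 FPKM in SCR. In all, 82 called genes lay above and 165 below all 6 control libraries, and over all tested genes the counts were 517 and 493, where chance gives 3.6% of genes in each direction.

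The p53 and immediate early lists were called lower in MEIS2_KD than in SCR by camera with the preset but not with an estimated correlation, and the apoptosis and stress lists were not called. Of 23 tested p53 target genes 6 fell and 0 rose, 8 fell when adjusted over the list alone (camera adjusted p = 0.00156; adjusted p = 0.0929 with an estimated correlation). The growth arrest gene GADD45A averaged 15.5 ± 0.483 FPKM in MEIS2_KD, 52.7 ± 5.64 in SCR and 15.8 ± 1.38 in untreated cells (SD, n = 2). BTG2 was at 5.98 and 5.45 FPKM in SCR, 0.0544 and 0 in MEIS2_KD, and 0.094 and 0 in untreated cells. Against untreated cells the p53 list had 0 calls and a median log2 difference of -0.026 (camera adjusted p = 0.812, and 0.276 against PLKO). In SCR against untreated it was higher (camera adjusted p = 0.00264, but adjusted p = 0.0851 with an estimated correlation). Of 21 tested immediate early genes 5 fell and 1 rose, or 7 and 1 when adjusted over the list alone (camera adjusted p = 0.00277; adjusted p = 0.172 with an estimated correlation). EGR1, an immediate early transcription factor, averaged 3.61 ± 0.487 FPKM against 45.4 ± 0.54 in SCR and 4.52 ± 0.425 in untreated cells, and KLF10 averaged 3.81 ± 0.199 against 8.26 ± 0.679 and 6.77 ± 0.632 (SD, n = 2). Of 27 tested apoptosis regulators 4 fell and 0 rose, likewise when adjusted over the list alone (camera adjusted p = 0.388), with MCL1 at 78.5 ± 3 against 111 ± 2.20 FPKM and BBC3 (PUMA) at 0.519 ± 0.229 against 2.82 ± 0.329 (SD, n = 2). The 27 tested genes of amino acid and unfolded protein stress had 4 lower and 1 higher, or 8 and 2 when adjusted over the list alone (camera adjusted p = 0.235). DDIT4 changed by -1.77 ± 0.134 and SDF2L1 by -0.64 ± 0.104 (log2, SE).

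Hypoxia, glycolysis and cholesterol genes were lower in MEIS2_KD than in SCR. Of 27 tested hypoxia and glycolysis genes 9 fell and 1 rose, or 12 and 1 when adjusted over the list alone, with a camera adjusted p of 4.1e-06 (adjusted p = 0.0707 with an estimated correlation). ALDOC, an aldolase, averaged 2.29 ± 0.185 FPKM in MEIS2_KD, 15.9 ± 3.58 in SCR and 8.65 ± 0.273 in untreated cells (SD, n = 2). PFKFB4, a regulator of glycolysis, averaged 3.10 ± 1.02, 11.5 ± 0.894 and 10.9 ± 0.701 FPKM in these groups, BNIP3 22.2 ± 2.60, 51.0 ± 2.54 and 41.0 ± 3.37, and the glucose transporter gene SLC2A3 8.45 ± 1.68, 22.9 ± 1.71 and 14.2 ± 0.384 (SD, n = 2). Of 22 tested cholesterol biosynthesis genes 2 fell and 0 rose, 8 fell when adjusted over the list alone, with a camera adjusted p of 0.00766 (adjusted p = 0.111 with an estimated correlation). INSIG1, a sterol sensor partner, averaged 27.1 ± 1.47 FPKM against 57.7 ± 2.20 in SCR, and STARD4 14.0 ± 0.0677 against 19.3 ± 0.684 (SD, n = 2).

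The remaining lists were not called by camera in this comparison. Of 20 tested genes linked to AML1-ETO 4 fell and 0 rose, or 4 and 2 when adjusted over the list alone (camera adjusted p = 0.388), with NFE2, UBASH3B and TRH among the falls, TRH being the thyrotropin-releasing hormone gene. Among 29 tested RUNX1 and ETS family factors 4 fell and 1 rose, or 5 and 2 when adjusted over the list alone (camera adjusted p = 0.975). The 12 Src family kinases and regulators gave 0 calls by limma, with 1 higher and 2 lower at an unadjusted p below 0.05 (camera adjusted p = 0.494), also when adjusted over the list alone, with LYN at 14.4 ± 1.28 FPKM against 19.4 ± 1.84 and BTK at 56.4 ± 6.96 against 45.1 ± 3.89 (SD, n = 2). Of 16 stem and progenitor genes 2 rose, the adhesion molecule genes CD44 (log2 0.51 ± 0.081) and ITGA6 (0.67 ± 0.123, SE), and adjusted over the list alone 2 rose and 2 fell (camera adjusted p = 0.727). Of 30 G1/S genes CDC45 fell (log2 -0.93 ± 0.127), also when adjusted over the list alone (camera adjusted p = 0.388), and GINS2 stood at 29.0 ± 0.129 against 39.9 ± 1.15 FPKM (SD, n = 2). Of 30 G2/M genes CCNF fell (log2 -0.59 ± 0.134), with 0 called when adjusted over the list alone and 2 higher and 3 lower at an unadjusted p below 0.05 (camera adjusted p = 0.975), and UBE2C stood at 86.3 ± 6.85 against 65.1 ± 0.516 FPKM (SD, n = 2). Of 30 MYC and ribosome biogenesis genes LDHA fell (log2 -0.48 ± 0.072), also when adjusted over the list alone (camera adjusted p = 0.231), and WDR74 stood at 36.2 ± 2.11 against 47.0 ± 0.0606 FPKM (SD, n = 2). Of 19 tested interferon-stimulated genes 2 fell, BST2 (log2 -3.62 ± 0.204) and IFITM1 (-1.99 ± 0.15), and 1 rose, the same counts when adjusted over the list alone (camera adjusted p = 0.975). Of 13 NF-kB and inflammatory genes TNFAIP2 (log2 -0.76 ± 0.147) and ICAM1 (-1.30 ± 0.256) fell, 2 also when adjusted over the list alone (camera adjusted p = 0.975). Of 8 tested lymphoid genes IGLL1 rose (log2 1.31 ± 0.27) and CD3D fell (-1.73 ± 0.2), also when adjusted over the list alone (camera adjusted p = 0.829). Median and mean differed in sign for the TALE and HOX (0.12 and -0.57), RUNX1 and ETS (0.05 and -0.26), interferon (0.05 and -0.22), NF-kB (0.08 and -0.09) and G2/M (0.003 and -0.015) lists.

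The SCR libraries stood apart from the others, so the calls against SCR were set beside the other controls. Spearman correlations of SCR with the 6 other libraries were 0.930 to 0.946, against 0.952 to 0.960 among those 6. Of the 614 genes lower in MEIS2_KD than in SCR, 18 were also called lower against untreated, 34 against PLKO, and 484 were called higher in SCR than in untreated cells. Their median log2 difference was -1.05 against SCR and -0.06 against untreated. Of the 165 genes higher than in SCR, 5 were called higher against untreated, 7 against PLKO, and 68 were called lower in SCR than in untreated cells. For both directions together, simulated unchanged groups sharing libraries gave on average 0.42, 0.34 and 0.24 shared calls in these 3 overlaps. Those simulated genes were independent, so the values may be too low. No simulated group differed, SCR included, so the values do not give the overlap to be met when SCR alone differs. With the SCR libraries left out, a fit chosen after seeing the data, MEIS2_KD against the mean of PLKO and untreated gave 60 calls in place of 779, 18 higher and 42 lower, 24 of them small RNA genes. MS4A3 (log2 0.97), S100A9 (1.69), S100A8 (1.41), BPI (1.01), MNDA (0.71) and LYZ (0.62) were among the higher genes in that fit. Their limma adjusted p ran from 0.0183 (MNDA) to 0.0497 (S100A9 and LYZ). Taken singly in the 4-group fit, PLKO gave a call for S100A9 only among these genes, and untreated for MNDA and LYZ only. MS4A3, S100A8 and BPI passed against neither. All had been picked for lying above all 6 control libraries, so the fit without SCR is no independent check of them. The other 6 of the 12 largest rises against SCR were not called there, with an adjusted p of 0.069 for SERPINA1, 0.258 for GFRA3, 0.37 for SERPINB8, 0.41 for CSTA, 0.729 for IGLL1 and 0.734 for CLEC12A, and of the 12 largest falls against SCR only HIST1H2BK (-1.02) was called. That fit still holds the PLKO libraries, in which HIST1H2BK is above untreated: against untreated alone it was not called (log2 -0.41, adjusted p = 0.268). HBG2, HBE1, HBZ, HBG1 and RHAG were also called lower in that fit (erythroid list camera adjusted p = 7.33e-16; adjusted p = 0.0595 with an estimated correlation), although listed at 0 in untreated cells. Leaving out SCR replicate 1 or 2 lowered the 779 calls to 367 and 431.

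**Figure D2:**
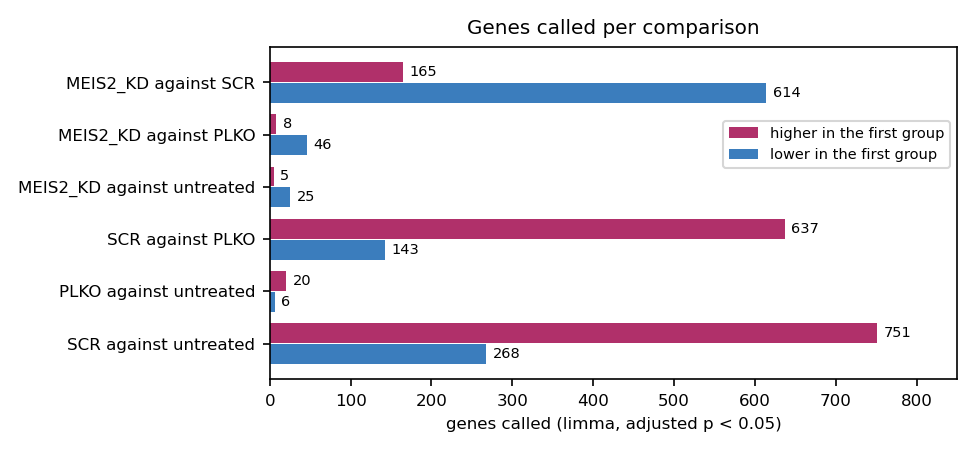
Number of genes called by limma at an adjusted p below 0.05 in each of the 6 comparisons, drawn as bars for genes higher and lower in the first group named. The 3 comparisons with SCR give 779, 780 and 1019 calls, and the 3 without it 54, 30 and 26.

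**Figure D3:**
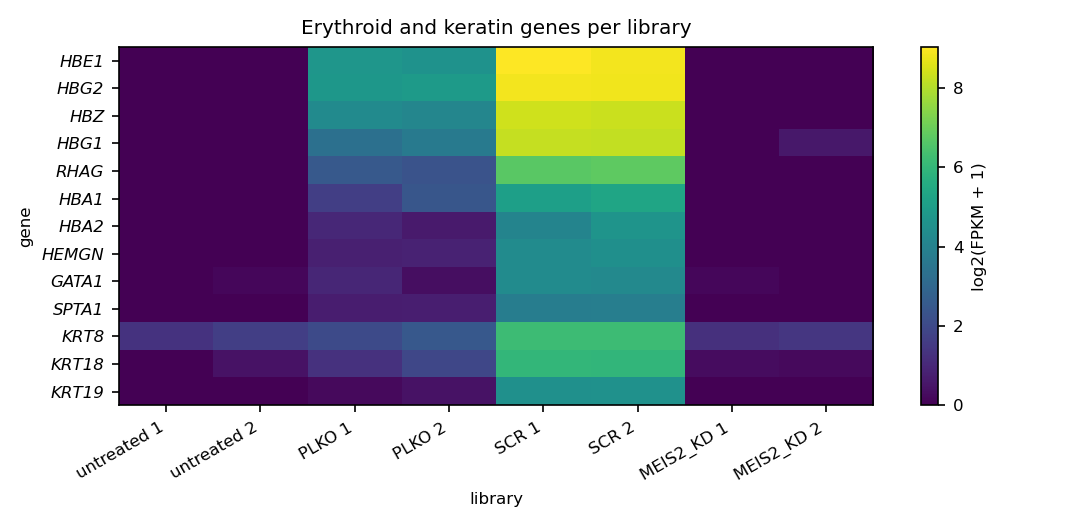
Colour gives log2(FPKM + 1) of 13 erythroid and keratin genes (top to bottom) in the 8 libraries (left to right). SCR libraries are highest, PLKO libraries lie between, and untreated and MEIS2_KD libraries are at or near 0 except for KRT8.

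Against the PLKO backbone, the libraries labelled MEIS2_KD had lower TRH, PFKFB4, BNIP3 and globin transcripts and higher S100A9 and HGF, a growth factor. TRH averaged 18.1 ± 0.592 FPKM in MEIS2_KD against 124 ± 4.06 in PLKO (SD, n = 2), a log2 change of -2.71 ± 0.08 (SE, limma adjusted p = 1.95e-06). HGF averaged 12.6 ± 1.03 against 5.29 ± 0.277 FPKM, and S100A9 14.2 ± 3.98 against 3.60 ± 0.347 (SD, n = 2). Of 54 calls 8 were higher and 46 lower, and 13 were small RNA genes, whose values rest on very short transcripts. The erythroid list fell (6 of 20 called lower, 15 adjusted over the list alone; camera adjusted p = 5.14e-25, and 0.00691 with an estimated correlation), led by HBG2, HBE1, HBZ and HBG1, which PLKO libraries hold and untreated libraries do not. HBG1 stood at 9.16 and 11.96 FPKM in PLKO and at 0 and 0.511 in MEIS2_KD.

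Hypoxia and cholesterol genes were lower than in PLKO and cell cycle genes higher as groups. The hypoxia and glycolysis list had 2 of 27 genes called lower, PFKFB4 and BNIP3, with 7 lower adjusted over the list alone (camera adjusted p = 6.21e-12, and 0.0283 with an estimated correlation). The cholesterol list had INSIG1 called lower, with 2 lower adjusted over the list alone (camera adjusted p = 5.01e-07, and 0.0306 with an estimated correlation), and the AML1-ETO list had TRH called lower, with 6 lower adjusted over the list alone (camera adjusted p = 1.39e-05, and 0.0396 with an estimated correlation). The G1/S list was higher with a median log2 difference of 0.14 and 0 members called, 5 of them higher at an unadjusted p below 0.05 (camera adjusted p = 6.77e-07, and 0.0396 with an estimated correlation). The G2/M list was higher with a median of 0.18 and 0 members called, 7 of them higher unadjusted (camera adjusted p = 6.46e-08; adjusted p = 0.153 with an estimated correlation). For the fibroblast and epithelial list, with 0 called and 2 lower unadjusted, camera gave an adjusted p of 0.000911 (adjusted p = 0.153 with an estimated correlation). The split of the 54 calls became 27 higher and 39 lower without MEIS2_KD replicate 2, and 14 and 28 with only the compared groups in the fit. With the SCR libraries out of the fit the 54 calls became 44, and with an estimated correlation the hypoxia, cholesterol, AML1-ETO and G1/S lists then gave adjusted p values of 0.0852, 0.0852, 0.0975 and 0.115. Their median log2 differences (-0.187, -0.227, -0.137 and 0.144) use only the MEIS2_KD and PLKO means. They could therefore not change when SCR left the fit.

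Against untreated cells, in which HBE1, HBG1, HBG2 and HBZ were listed at 0, TRH, PFKFB4, ALDOC, CD300A and C1QTNF4 showed the largest falls in the libraries labelled MEIS2_KD, small RNA genes and unnamed loci passed over (C19orf77 fell by 1.76 on the log2 scale), and HGF, MNDA and LYZ rose. TRH averaged 18.1 ± 0.592 FPKM against 109 ± 3.14 and C1QTNF4 94.0 ± 11.7 against 249 ± 10.6 (SD, n = 2). CD300A, an inhibitory receptor of leukocytes, averaged 2.62 ± 0.756 against 8.97 ± 0.356 FPKM (SD, n = 2). CTSG, the granule protease cathepsin G, fell by 1.07 on the log2 scale (117.9 ± 3.85 against 249 ± 4.87 FPKM; SD, n = 2), while LYZ rose by 0.71 and MNDA by 0.77. In total 30 genes were called by limma, 5 higher and 25 lower, 5 of them small RNA genes.

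The hypoxia, cholesterol, AML1-ETO, G1/S and G2/M lists were called against untreated cells as well. The hypoxia and glycolysis list was lower, with BNIP3, ALDOC and PFKFB4 called and 8 lower adjusted over the list alone (camera adjusted p = 9.11e-10, and 0.0279 with an estimated correlation). The cholesterol list (INSIG1 called, 2 lower adjusted over the list alone; camera adjusted p = 5.12e-07) and the AML1-ETO list (TRH called, 6 lower adjusted over the list alone; camera adjusted p = 3.69e-07) were also lower, each with an adjusted p of 0.0279 with an estimated correlation. The G1/S list was higher, with a median log2 difference of 0.20, 0 members called, 1 higher adjusted over the list alone and 11 unadjusted (camera adjusted p = 5.32e-09, and 0.0279 with an estimated correlation). The G2/M list had a median of 0.28 and 0 members called, 18 of them higher unadjusted (camera adjusted p = 6.09e-13; adjusted p = 0.0852 with an estimated correlation). Lists called by camera with the preset but not with an estimated correlation were the RUNX1 and ETS factors, stem and progenitor genes and MYC genes (each adjusted p = 0.0911 with an estimated correlation), interferon genes (adjusted p = 0.0852 with an estimated correlation), immediate early genes (adjusted p = 0.117 with an estimated correlation) and megakaryocyte genes (adjusted p = 0.197 with an estimated correlation). The count of 30 became 17 without untreated replicate 2, 12 without either SCR library, 12 without both, and 71 without MEIS2_KD replicate 1. The split became 21 higher and 23 lower without MEIS2_KD replicate 2, and 12 and 11 with only the compared groups in the fit. With the SCR libraries out of the fit, the hypoxia, cholesterol and AML1-ETO lists had an adjusted p of 0.0872 with an estimated correlation, and the G1/S list 0.0949. Their median log2 differences (-0.205, -0.171, -0.158 and 0.201) use only the MEIS2_KD and untreated means. They could therefore not change when SCR left the fit.

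Calling the same direction against all 3 controls left 19 genes, 16 lower and 3 higher. The lower genes were TRH, C19orf77, PFKFB4, CD300A, C1QTNF4, MIR210HG, FGF11, P4HA2, SERPINE2, BNIP3, SLC18A2, TXNIP, PRDM8, INSIG1, TMSB10 and DAZAP2, of which those outside the fixed naming rule are named after their values were seen. MIR210HG, the host transcript of a hypoxia-induced microRNA, averaged 0.664 ± 0.113 FPKM against 3.25 ± 0.48 in untreated cells, and P4HA2, a collagen prolyl hydroxylase, 1.97 ± 0.0813 against 4.78 ± 0.618 (SD, n = 2). SLC18A2, a monoamine transporter, averaged 17.3 ± 1.87 against 32.1 ± 1.45 FPKM, and TXNIP, a thioredoxin inhibitor, 249 ± 14.8 against 408 ± 6.96 (SD, n = 2). Apart from 2 small RNA genes, HGF was the higher gene, with a log2 change of 0.68 ± 0.122 against SCR, 1.11 against PLKO and 1.14 against untreated. Unchanged groups sharing the MEIS2_KD libraries gave a mean of 0.2 such genes and at most 2 in 50 simulated sets. The simulated genes were independent and carried no shared library effect, so these numbers may be too low. SCR did not differ from the other groups in those sets, so they are no baseline for data with SCR apart. Calls shared between PLKO and untreated numbered 24, where unchanged groups gave 0.32 on average and independent lists 0.00343 higher and 0.0987 lower genes; part of the excess may come from the shared MEIS2_KD libraries, since they could not be split. The 19 genes became 3 to 33 when any library was left out (3 without either SCR library, 33 without MEIS2_KD replicate 1, of which 10 higher and 23 lower), with more higher (19) than lower (13) genes without MEIS2_KD replicate 2, and 6 against PLKO and untreated with SCR out of the fit: TRH, C1QTNF4, CTSG and 3 small RNA genes. In the fit against the mean of PLKO and untreated, 18 of the 19 were called. The 19 had been picked by calls against these same PLKO and untreated libraries, so that fit is no independent check of them.

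**Figure D4:**
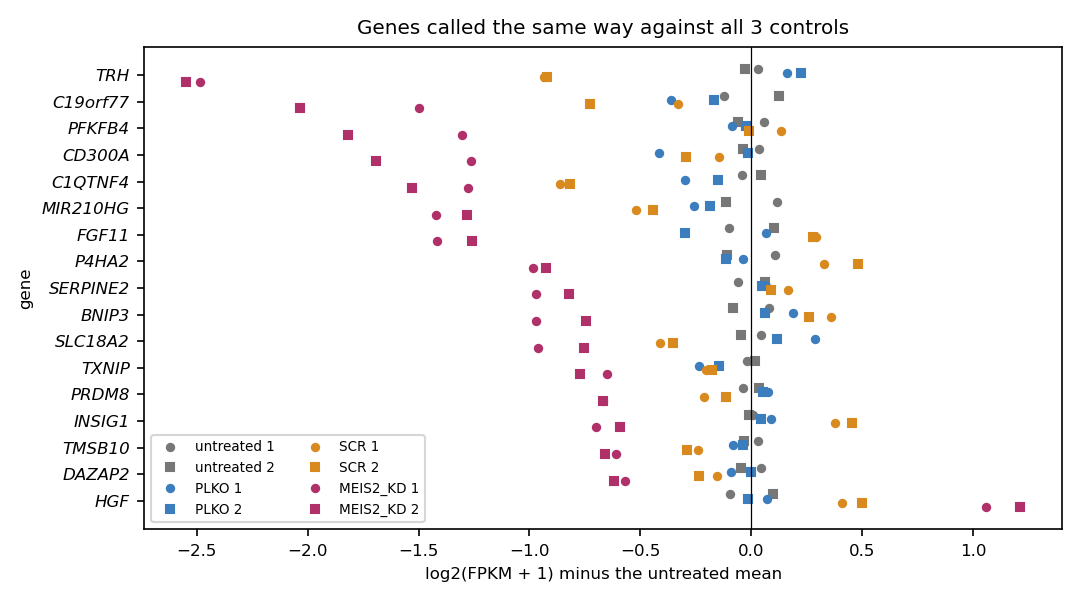
Difference of log2(FPKM + 1) from the mean of the untreated libraries for the 17 genes, small RNA genes left out, called the same way against all 3 controls, with a point per library. MEIS2_KD points lie left of the controls for 16 genes and right of them for HGF.

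The scrambled shRNA was compared with the backbone and with untreated cells as background. Erythroid genes and keratins were higher in SCR than in either, and the primary granule gene CTSG was lower. Against PLKO 780 genes were called, 637 higher and 143 lower, and against untreated 1019, 751 higher and 268 lower. NMU, a neuropeptide, was at 49.8 and 46.4 FPKM in SCR against 0.671 and 0.745 in PLKO and 0 and 0.237 in untreated cells, KRT18 at 62.7 and 60.7 against 1.47 and 2.80 and against 0 and 0.359, and HBG1 at 298 and 292 FPKM. CTSG averaged 93.6 ± 1.67 FPKM in SCR, 227 ± 17.4 in PLKO and 249 ± 4.87 in untreated cells, CST7 1.71 ± 0.136, 5.37 ± 1.60 and 5.98 ± 0.248, and MFAP4 4.86 ± 1.32, 12.1 ± 4.33 and 14.2 ± 1.52 (SD, n = 2). TRH (56.6 ± 0.366 FPKM) and TARP (2.11 ± 0.966) were among the 5 largest falls against PLKO, and IGLL1 and MS4A3 against untreated, small RNA genes passed over.

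By list, 17 of 20 erythroid genes rose and 1 fell in both comparisons, with a camera adjusted p of 6.52e-22 against PLKO (0.00898 with an estimated correlation) and 2.32e-22 against untreated (0.00863 with an estimated correlation). Primary granule genes fell, 6 of 15 against PLKO (camera adjusted p = 7.88e-08; adjusted p = 0.0533 with an estimated correlation) and 8 of 15 against untreated (1.72e-08, and 0.0457 with an estimated correlation). Against untreated the G1/S and G2/M lists each had 6 genes higher and 0 lower, with adjusted p = 0.0826 and 0.179 with an estimated correlation. The 2 comparisons shared 659 calls, 552 higher and 107 lower, where unchanged groups sharing the SCR libraries gave 0.22 on average and independent lists 41.1 and 3.29. The value of 0.22 comes from independent simulated genes in groups that did not differ, and may be too low. The count against PLKO moved with every library left out, from 314 without SCR replicate 1 to 1200 without MEIS2_KD replicate 1. The count against untreated moved with each SCR, untreated and MEIS2_KD library, from 335 without SCR replicate 1 to 1645 without MEIS2_KD replicate 2.

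Globin transcripts, RHAG and HIST1H2BK were higher in PLKO than in untreated cells. PLKO against untreated gave 26 calls, 20 higher and 6 lower, of which 12 were small RNA genes, including all 6 lower. HBG2, HBE1, HBZ, HBG1 and RHAG were the 5 largest rises once small RNA genes were passed over, RHAG standing at 4.78 and 3.91 FPKM in PLKO and at 0 in untreated cells. HIST1H2BK differed by 1.23 ± 0.108 on the log2 scale (SE). Of the 20 erythroid genes 6 rose, 12 adjusted over the list alone (camera adjusted p = 3.43e-25, and 0.00681 with an estimated correlation). The G2/M list had 0 members called, 1 higher unadjusted, and a camera adjusted p of 0.00737 (adjusted p = 0.368 with an estimated correlation). Without PLKO replicate 1 or 2 the count became 43 and 40, and without small RNA genes 13.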

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

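Leaving out the SCR libraries and leaving out small RNA genes were chosen after the data were seen; the other alternatives were fixed beforehand. The MEIS2 difference stayed below 0 and uncalled under all 20 alternatives. Several of these, such as leaving out an untreated or PLKO library, cannot change the difference from SCR itself (-0.42), only its p-value. Over all settings against SCR the difference ran from -0.65 (without MEIS2_KD replicate 2) to -0.19 (without MEIS2_KD replicate 1). It was -0.24 against the mean of the 3 control groups. With SCR left out it was -0.15 against the mean of PLKO and untreated. An edgeR test on recovered reads was not run, because whole reads were not recovered. Read depth is unknown, which leaves genes of few fragments least certain. The cause of the changes below was not tested.

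Without a filter on low values the calls were 1331 for MEIS2_KD against SCR, 11 against untreated, 1267 for SCR against PLKO, 1530 for SCR against untreated, and 6 against all 3 controls. At a mean of at least 5 FPKM, with fewer genes tested, they were 418, 443 for SCR against PLKO and 677 for SCR against untreated. Without trend or robust, MEIS2_KD against untreated gave 13 and all 3 controls 7. With only the compared groups in the fit MEIS2_KD against SCR gave 466 and SCR against untreated 2040. MEIS2_KD against the mean of the 3 control groups gave 287. Without small RNA genes PLKO against untreated gave 13. With SCR left out MEIS2_KD gave 60 against the mean of PLKO and untreated, 44 against PLKO and 12 against untreated, and these last comparisons shared 6. Quantile scaling turned the split of MEIS2_KD against SCR from 165 higher and 614 lower to 226 and 587, of SCR against untreated from 751 and 268 to 674 and 450 (637 and 428 with upper quartile scaling), and of SCR against PLKO from 637 and 143 to 602 and 241 (529 and 210).

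The replicate block changed the calls from 779 to 536, 54 to 33, 30 to 10, 780 to 471, 26 to 23, 1019 to 604 and, against all 3 controls, 19 to 4. Deviations of same-numbered libraries correlated at -0.067 to 0.048, so no pairing by number was seen over all tested genes. Such a correlation cannot exclude a batch that affects some genes. Leaving out a library gave 367 to 933 calls for MEIS2_KD against SCR, 40 to 66 against PLKO, 12 to 71 against untreated, 314 to 1200 for SCR against PLKO, 27 to 43 for PLKO against untreated, 335 to 1645 for SCR against untreated, and 3 to 33 against all 3 controls; a lone library is then assumed to vary like the other groups.

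With SCR left out the direction reversed for RUNX1 (-0.06), RUNX1T1 (-0.10), YES1 (0.04), CDC45 (0.23), GINS2 (0.02), CCNF (0.09), SDF2L1 (0.26), CTSG (-1.01), CST7 (-1.18) and MFAP4 (-0.61), and against the mean of the 3 control groups for CTSG (-0.56), CST7 (-0.75) and MFAP4 (-0.19). CST7 ran from -0.23 to 0.44 when a library was left out. Of 78 named genes called against SCR, 48 lost the call with SCR left out, 26 without SCR replicate 1, 19 without SCR replicate 2, 8 with the replicate block and 21 with only the compared groups.

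Camera reversed for 9 lists against other controls, with adjusted p given for SCR left out, PLKO and untreated in turn. For RUNX1 and ETS factors it was 0.0194, 0.102 and 0.0131, and for stem cell genes 0.0762, 0.281 and 0.0103. With an estimated correlation RUNX1 and ETS factors lost these calls (camera adjusted p = 0.154 with SCR left out and 0.0911 against untreated). Stem cell genes did too (0.0911 against untreated). The preset gave 0.738, 0.534 and 0.997 for Src kinases and 0.738, 0.853 and 0.273 for primary granule genes. It was 1.34e-08, 6.77e-07 and 5.32e-09 for G1/S genes, 4.24e-11, 6.46e-08 and 6.09e-13 for G2/M genes, and 0.0182, 0.112 and 0.00963 for MYC genes. G1/S genes lost the call with SCR left out with an estimated correlation (camera adjusted p = 0.0744). They kept those against PLKO (0.0396) and untreated (0.0279). G2/M genes lost every such call (0.149, 0.153 and 0.0852 in turn). MYC genes lost theirs too (0.154 with SCR left out and 0.0911 against untreated). The preset gave 0.269, 0.112 and 0.626 for stress genes and 0.412, 0.911 and 0.136 for lymphoid genes. Under fry the RUNX1 and ETS (0.00262) and lymphoid (0.731) lists reversed, and with the replicate block the RUNX1 and ETS and NF-kB lists (both 0.987). Of 9 lists called by camera against SCR, 1 (erythroid) was called with an estimated correlation. Under fry all 9 stayed called, and 7 lists not called by camera were called in the same direction.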

Other observations

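The test of added marker genes was fixed before their values were seen; the other tests below were chosen after the results were seen.

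Outside the fixed rule, C3, a complement component, stood at 2.64 and 2.39 FPKM in the libraries labelled MEIS2_KD against 0.655 to 0.908 in the 6 control libraries. It was called against SCR (log2 0.96, limma adjusted p = 0.00795) and, with SCR left out, against the mean of PLKO and untreated (log2 0.97, adjusted p = 0.038), and it was picked after its values were seen. The higher myeloid genes of that fit (MS4A3, S100A8, S100A9, BPI, MNDA and LYZ) stood beside a lower CTSG (log2 -1.01), so genes of neutrophil granules did not all move one way. CST7, another granule cell gene, was at 1.31 and 2.68 FPKM in MEIS2_KD against 6.15, 5.80, 6.51 and 4.24 in untreated and PLKO libraries, and was not called (adjusted p = 0.162). Of 30 G2/M genes 16, and of 30 G1/S genes 11, were higher in both MEIS2_KD libraries than in all 4 untreated and PLKO libraries, and 0 were lower, where chance gives 6.67% of genes in each direction. That share takes genes as independent, whereas the estimated correlation of the G2/M list was 0.147. SCR also lay above untreated, with median log2 differences of 0.311 for G2/M and 0.275 for G1/S. Against SCR the MEIS2_KD medians were 0.003 and -0.031, so the higher levels were shared with the SCR libraries, which also held transcripts of open origin (below). Against PLKO the MEIS2_KD medians were 0.179 for G2/M and 0.144 for G1/S.

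A set of 34 genes, among them HBE1, HBG2, RHAG and KRT18, had a mean below 0.5 FPKM in untreated and in MEIS2_KD and at least 10 in SCR. Their summed FPKM was 2322 in SCR, 110.7 in PLKO, 0.722 in untreated and 1.08 in MEIS2_KD. For the K562 line as their origin, 7 added marker genes were examined. The bound was at least 1 FPKM in SCR and at least 5 times untreated. By the rule fixed before, 2 or fewer genes meeting it counted against K562, and 2 did (IGF2BP1 and TFR2). That rule was a poor one, because LIN28B (7.74 and 7.37 FPKM), IGF2BP3 (17.7 and 17.4) and TRIM58 (2.33 and 1.68) were already present in untreated cells. The origin is therefore left open, although the rule as written went against K562. LIN28B stood at 14.9 and 15.8 FPKM in SCR and TRIM58 at 4.93 and 5.92, whereas IGF2BP3 (17.1 and 19.4) was near its untreated level, GAGE1 reached 0.526 and 0.118 and GAGE12J was listed at 0. A single foreign source of RNA is a candidate explanation that the ratios cannot decide. Of the 34 genes, 82.4% had a PLKO to SCR ratio within 2-fold of the median (4.01%), but carry-over would give this too. A response of Kasumi-1 cells to the scrambled shRNA stays open too: 91.2% of the genes were higher in both PLKO libraries than in all 4 untreated and MEIS2_KD libraries, but carry-over from SCR into PLKO would give this and the fixed ratio whatever the origin. An exchange of SCR and MEIS2_KD labels was not settled by MEIS2, whose lower SCR value (5.84 FPKM) lay above the highest of untreated and PLKO (5.52) without a call (adjusted p = 0.369 against PLKO and 0.419 against untreated).

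Small RNA genes made up 11 of the 779 calls against SCR, and 8 of these were listed at 0 in both libraries of a group. They may rest on 1 or 2 fragments each: the replicates of the other group held the same number of fragments, within 2%, for 62.5% of the 8, for example 34.3 and 49.2 FPKM for MIR181B1 in MEIS2_KD. With ratios of 2 to 1 or 1 to 2 counted as well, 7 of the 8 had such numbers. The ratios do not give the number of fragments itself, so chance detection and a real difference cannot be told apart for these 8 genes. No biological explanation was tested.

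Hypoxia and glycolysis genes were lower in MEIS2_KD. The transcripts that set SCR apart are argued against as the whole cause, because the list was also lower against untreated cells, a difference taken without SCR values (camera adjusted p = 9.11e-10, and 0.0279 with an estimated correlation). With SCR out of the fit the adjusted p was 6.68e-09 by camera and 0.0102 by fry, but the call was lost with an estimated correlation (adjusted p = 0.0872). The median log2 difference of the list was -0.205 in both fits. It could not change, because it uses only the MEIS2_KD and untreated means, so its sameness is no test. Loss of MEIS2 is the biological explanation the design names: of the 9 members called against SCR, 33.3% were lower in MEIS2_KD replicate 1, which had less MEIS2 transcript, than in replicate 2. A single library on each side cannot decide this, so it stays open, as do culture conditions such as cell density or oxygen, which were untested.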
